A study of Oryza sativa with 5 samples.

How the data were processed

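Chromatin of rice male meiocytes (pollen mother cells) at early prophase I was trimmed with micrococcal nuclease, sonicated and precipitated with antibodies against H3K4me3 or H3K27me3, per the labels' protocols, which state that each antibody was used on biological replicates. Of 5 samples, the 4 immunoprecipitated libraries (2 per mark) were analysed. The input library was not analysed here. Groups and replicate numbers were taken from the sample titles.

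Each of the 4 libraries has its own deposited list of peaks. Whether each list was called from that library alone is not stated in the sources used here. The submitters' processing notes name fastp, Bowtie2, Picard, SAMtools, deepTools and MACS2. Their versions, the control and the calling thresholds are not given in the sources used here, nor is the genome build. The H3K4me3 lists are narrow peaks with a summit and the H3K27me3 lists broad peaks without. The peak names in the deposited lists carry different tags for the 4 libraries, 1 of them the word subsample and another the word merge, so the libraries may have been handled in different ways before calling, and the tags do not say more. The deposited fold enrichment of each peak is a ratio over the caller's background, by the authors, and was used only to describe, rank and match peaks within 1 list. The deposited significance values are −log10 p and −log10 q as the authors' caller wrote them. The smallest −log10 q was close to 2 in the H3K4me3 lists and close to 1 in the H3K27me3 lists. The deposited score is 10 times the −log10 q, cut to a whole number, in all H3K4me3 peaks and in 19771 of 19774 and 19448 of 19450 H3K27me3 peaks, and was not used further. A looser threshold for H3K27me3 admits weaker peaks, and the median −log10 q was 17.8 and 6.42 in the H3K4me3 lists against 2.98 and 2.72 in the H3K27me3 lists. The share of peaks with a −log10 q of at least 5 was 95.8% and 71.9% for H3K4me3 and 24.4% and 17.1% for H3K27me3. Whether the q of a broad peak without a summit is on the same scale as that of a narrow peak is not known here. Depth in reads is unknown, and a deeper library yields more and wider peaks, so differences in peak number between replicates are not differences in the chromatin alone.

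Intervals were handled with Python 3.11.15 and numpy 2.4.6, statistics used scipy 1.17.1 and figures matplotlib 3.10.9. Peaks counted as shared with at least 1 bp in common. Consensus regions of a mark, called the regions of that mark, are the bases covered in both replicates. Chromosome lengths were taken as the last peak end over the 4 lists, 372.8 Mb in all. Random expectation came from 100 placements with lengths kept, anywhere on the same chromosome or within 500 kb. These placements permute positions, and their two-sided permutation p cannot go below 0.020. Placements ignore assembly gaps, in which no peak can be called, and repeats, in which peaks may be missed. The expectation over whole chromosomes may therefore be too low and that within 500 kb less so. Ranks and windows were tested by 1000 rotations of labels along the genome, with a smallest two-sided p of 0.0020. Marks were compared by an exact permutation test of 2 against 2 libraries. Peaks, regions and windows are not replicates, so these p-values describe the lists and not a wider population of plants. Windows were 100 kb, boundaries were those of H3K27me3 regions of at least 2000 bp with 500 bp on either side, and the centre of an H3K4me3 region or the summit of a peak gave its position.

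The interval code was tested on simulated lists. For H3K4me3 lists with 60% planted shared peaks, 63.1% were recovered against 63.4% calculated for planting plus chance, and for H3K27me3 lists 64.7% against 64.7%. Regions placed independently of H3K4me3 gave a mean ratio of 1.01. With 10% of the H3K27me3 regions centred on H3K4me3, the ratio was 2.11 against 1.97 calculated.

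Sharing between replicates, shared bases, marks by chromosome, and peak width and rank were fixed before the data were examined. The comparisons by region length, of ranks of H3K4me3 peaks overlapping H3K27me3, at boundaries, in windows and of the unshared H3K27me3 peaks were chosen after. Results on genes had also been fixed: peaks at gene starts, marked genes, genes with both marks, and tests of 7 lists of gene symbols and 34 lists by product name. They were not made. The only gene table used here is on the assembly ASM3414082v1, and the lists do not lie on it: 16.6% of the summits of H3K4me3 replicate 1 fell within 500 bp of a gene end in that table, against 14.4% of random positions, and coordinates were not converted. No gene, exon, intron or UTR is therefore named. The rule that would have named genes was applied to regions: the 10 widest H3K4me3 regions, the 10 longest H3K27me3 regions and the 10 longest stretches with both marks. The alternatives tried were overlap of at least 50% of both peaks, a −log10 q of at least 5, leaving out each replicate of each mark, placement within 500 kb, region lengths of 1000 and 5000 bp and windows of 500 kb.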

Results

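Histone H3 trimethylated at lysine 4 (H3K4me3), a mark usually found at active gene starts, and histone H3 trimethylated at lysine 27 (H3K27me3), a mark deposited by Polycomb repressive complex 2, were mapped by chromatin immunoprecipitation and sequencing from small numbers of rice male meiocytes (pollen mother cells) in early prophase I. The series held 5 samples: 2 replicate libraries for each of the 2 marks, which the labels describe as biological replicates, and 1 input library, which was not analysed here. Each of the 4 immunoprecipitated libraries came as its own list of peaks, so read depth is unknown and every value below describes called peaks, not read coverage. Positions are given as in these lists, on 12 chromosomes. The genome build is not given in the sources used here, so no position was assigned to a gene.

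The first comparison asked how far the replicates of each mark found the same sites. Of the 29941 H3K4me3 peaks of replicate 1, 79.4% (95% Wilson interval 78.9 to 79.8%) overlapped a replicate 2 peak by at least 1 bp, and of the 27411 peaks of replicate 2, 93.3% (93.0 to 93.6%) overlapped a replicate 1 peak. For H3K27me3 the shares were 67.2% (66.6 to 67.9%) of 19774 peaks in replicate 1 and 79.8% (79.2 to 80.3%) of 19450 peaks in replicate 2. Random placement of the other replicate's peaks on the same chromosomes gave means of 8.29% and 9.01% for H3K4me3 and 11.4% and 11.7% for H3K27me3, and none of 100 placements reached an observed share (permutation p = 0.020 in each of the 4 lists, the smallest these placements can give). The intervals cover counting error only, and neighbouring peaks are not independent. When an overlap had to span at least 50% of both peaks, the H3K27me3 shares were 42.2% and 42.9%, against 64.8% and 70.8% for H3K4me3.

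In each list the peaks with the highest fold enrichment, as the authors' peak caller gave it, were found in the other replicate more often than those with the lowest. In H3K4me3 replicate 1 the shared percentage was 96.2% in the highest and 54.5% in the lowest of 4 equal groups of peaks by fold, and in H3K27me3 replicate 1 it was 93.5% and 32.3%. The gap was smaller in the second replicates, with 97.1% and 90.0% for H3K4me3 and 96.7% and 70.3% for H3K27me3. Shared peaks were also wider than unshared ones in every list, with median widths of 630 bp against 335 bp and 446 bp against 267 bp for H3K4me3, and of 1047 bp against 420 bp and 772 bp against 333 bp for H3K27me3. Among peaks with a −log10 q of at least 5, the gap between the highest and lowest groups in the replicate 2 lists came to 1.58 percentage points for H3K4me3 and 1.31 points for H3K27me3. The rise was not steady in H3K27me3 replicate 2, where the shares from the lowest to the highest group were 70.3, 68.3, 83.9 and 96.7%, and 88.2, 76.8, 74.1 and 89.5% with that threshold.

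**Figure D1:**
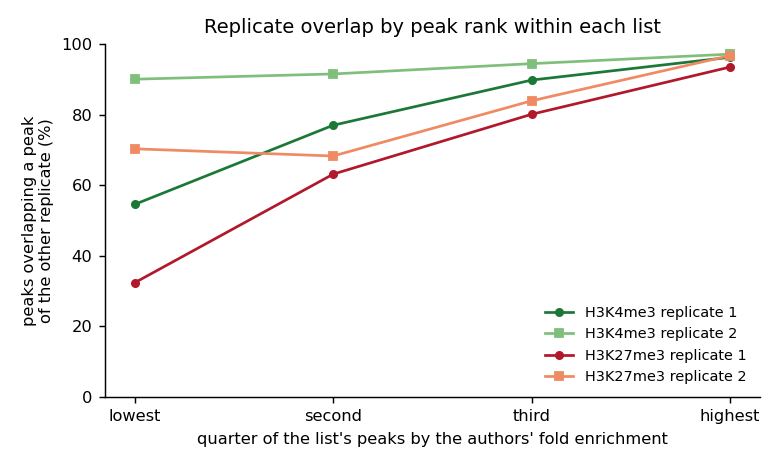
Percentage of peaks that overlapped a peak of the other replicate by at least 1 bp (vertical axis), in 4 equal groups of each list's peaks ranked by the authors' fold enrichment (horizontal axis), with 1 line for each of the 4 peak lists. The highest groups lie between 93.5% and 97.1%, and the lowest between 32.3% and 90.0%.

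At the authors' thresholds H3K4me3 formed more and narrower peaks, and H3K27me3 covered more of the genome with fewer and longer ones. The mean number of peaks per library was 28676 ± 1789 for H3K4me3 and 19612 ± 229 for H3K27me3, the median width was 500 ± 99 bp and 676 ± 81 bp, and the covered length was 16.3 ± 3.95 Mb and 23.4 ± 3.17 Mb (mean ± SD, n = 2 libraries per mark). Both H3K27me3 libraries lay on the same side of both H3K4me3 libraries in each measure. With 2 libraries against 2, an exact permutation test cannot go below p = 0.333 (two-sided), which was the value obtained for peak number, width and covered length. With the same cut, a −log10 q of at least 5, in all lists the order of the covered length reversed. It was 14.7 ± 5.70 Mb for H3K4me3 and 11.1 ± 3.06 Mb for H3K27me3 (exact permutation p = 0.667). The median widths were 533 ± 71 bp and 1886 ± 138 bp. The q of a narrow peak and that of a broad peak may not be on the same scale, so the cut need not be equally strict for both marks. The longest peaks measured 3657 bp and 2875 bp in the H3K4me3 lists and 40853 bp and 29037 bp in the H3K27me3 lists. The lists were called with different thresholds and formats for the 2 marks, narrow peaks for H3K4me3 and broad peaks for H3K27me3, so that width, number and covered length depend on the caller's settings as well as on the chromatin.

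Bases covered in both replicates were taken as the regions of a mark. H3K4me3 had 25715 such regions covering 12.2 Mb, or 3.28% of the 372.8 Mb spanned by the peaks, with a median of 419 bp, and only 11 of them reached 2000 bp. H3K27me3 had 16414 regions covering 17.5 Mb (4.70%), with a median of 606 bp. Of these, 2146 were at least 2000 bp long and held 46.6% of the H3K27me3 bases, and 372 were at least 5000 bp long and held 16.1%. The ratio of bases covered in both replicates to bases covered in either was 0.597 for each mark.

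The 10 widest H3K4me3 regions measured 2058 to 2445 bp, lay on chromosomes 1, 3, 4, 5 and 12, and none of them touched an H3K27me3 region. Of all H3K4me3 regions only 13.9% touched one, so 10 regions are too few to show avoidance. The second widest overlapped a peak of H3K27me3 replicate 1 alone. The widest lay on chromosome 1 at 30144264 to 30146708, followed by chromosome 3 at 1406126 to 1408521 and chromosome 12 at 2251601 to 2253849. Over the whole lists median width rose with fold, between the lowest and highest of 4 groups, from 367 to 700 bp in replicate 1 and from 358 to 524 bp in replicate 2. Among these 10 regions fold varied widely. The widest ranked in the 89.7th and 73.3rd percentile of fold. The chromosome 5 region at 25804937 to 25807038 ranked in the 87.3rd and 85.7th percentile of fold in the 2 H3K4me3 lists, whereas the chromosome 4 region at 24095903 to 24098116 ranked in the 34.1st and 22.2nd.

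The 10 longest H3K27me3 regions measured 14980 to 29037 bp, and their peaks lay in the 93.9th to 99.8th percentile of fold in the 2 lists. The longest covered chromosome 9 from 15808093 to 15837129, in the 99.5th and 99.0th percentile of fold in the 2 lists. It was followed by chromosome 7 from 1547586 to 1572310 (24725 bp) and chromosome 3 from 9344628 to 9364741 (20114 bp). Chromosome 9 held 3 of the 10 and chromosome 3 another 3. Across these 10 regions H3K4me3 occupied 3.14% of the bases, and 7 of the 10 overlapped at least 1 H3K4me3 region. The most were the 5 regions overlapping the one on chromosome 1 from 42199082 to 42214339, while the region on chromosome 3 from 6028630 to 6045162 (16533 bp) was 1 of the 3 that overlapped none.

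The second comparison asked whether the 2 marks were found at the same sites. The regions of both marks shared 1.32 Mb, which was 7.53% of the H3K27me3 bases and 10.8% of the H3K4me3 bases. These shares moved with the lists used: with H3K27me3 replicate 1 alone the marks shared 2.36 Mb and 19.3% of the H3K4me3 bases, and with H3K4me3 replicate 1 alone 12.01% of the H3K27me3 bases. With peaks of a −log10 q of at least 5 the shares were 4.11% of the H3K27me3 bases and 3.16% of the H3K4me3 bases. Placing the H3K27me3 regions at random on their chromosomes gave a mean of 3.29% (range 3.09 to 3.49% over 100 placements), so the observed overlap was 2.29 times the random one (permutation p = 0.020, the smallest the placements can give). Placed within 500 kb of their own position, which keeps each region in its own part of the chromosome, they gave 3.83% and a ratio of 1.96. For each pairing of single libraries the ratio within 500 kb was 2.63 and 2.49 for H3K27me3 replicate 1 with H3K4me3 replicates 1 and 2, and 1.70 and 1.82 for H3K27me3 replicate 2. With peaks of a −log10 q of at least 5 alone, 2787 H3K27me3 regions remained and the ratio within 500 kb was 1.28.

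The overlap was greatest in short H3K27me3 regions. Relative to placement within 500 kb, the share of bases in H3K4me3 was 2.66 times the placed value in regions under 500 bp, 3.33 times at 500 to 1000 bp, 2.30 times at 1000 to 2000 bp and 1.32 times at 2000 to 5000 bp (permutation p = 0.020 each). In regions of 5000 bp and over the share was 3.65%, against 4.17% placed, a ratio of 0.875 (permutation p = 0.040). This last value depended on the H3K4me3 lists, being 1.06 without H3K4me3 replicate 1 and 0.926 without replicate 2 (permutation p = 0.42 and 0.14). It was also a deficit in bases and not in regions touched. Of the regions of 5000 bp and over, 49.7% touched H3K4me3, against 47.2% placed. With a −log10 q of at least 5 these were 33.8% and 39.9%. Without H3K27me3 replicate 2 the ratio at 1000 to 2000 bp was 3.80. With a −log10 q of at least 5 that of the 191 regions under 500 bp was 1.09 (permutation p = 0.77), and only 8 of them touched H3K4me3. In the longer classes, in order of length, that threshold gave 3.11, 2.41, 1.26 and 0.718 (permutation p = 0.020, 0.020, 0.040 and 0.020).

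**Figure D2:**
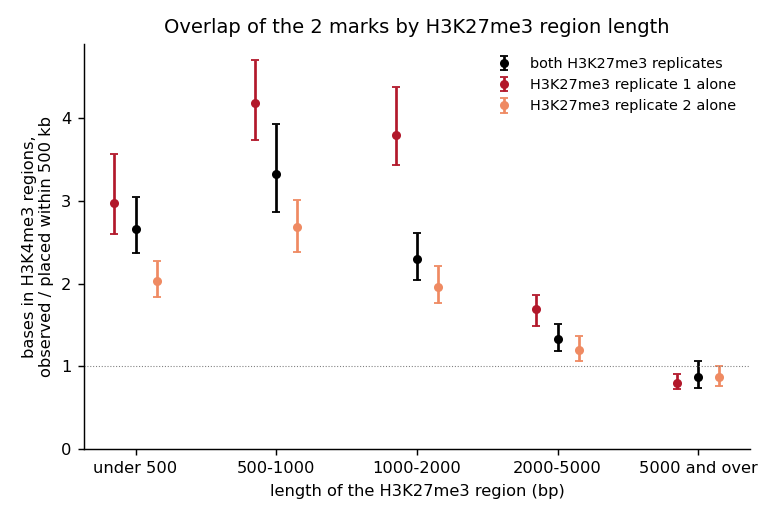
Share of H3K27me3 bases inside H3K4me3 regions, divided by the mean share after placement within 500 kb (vertical axis, 1 means no difference), by length of the H3K27me3 region in bp (horizontal axis). Points are the ratio to the mean of 100 placements, and bars run from the ratio to the highest placement to the ratio to the lowest. Black, regions of both replicates, falls from 3.33 at 500 to 1000 bp to 0.875 at 5000 bp and over. Red and orange are the peaks of H3K27me3 replicates 1 and 2 alone.

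Stretches carrying both marks were short. There were 3598 of them with a median of 316 bp, and 52 reached 1000 bp. The longest lay on chromosome 6 at 1040062 to 1041921 (1860 bp), where the H3K27me3 peaks ranked in the 97.2nd and 92.7th percentile of fold and the H3K4me3 peaks in the 18.9th and 22.9th. The next lay on chromosome 12 at 4252940 to 4254689 (1750 bp), chromosome 11 at 25276198 to 25277845 (1648 bp) and chromosome 1 at 39725229 to 39726846 (1618 bp). On chromosome 2 at 35848035 to 35849628 (1594 bp) the ranks were 32.8 and 86.4 in the H3K4me3 lists and 77.7 and 12.3 in the H3K27me3 lists, so that the replicates of each mark differed in rank here. Both marks were measured in a population of cells, and peak lists do not tell whether they sat on the same molecules.

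H3K4me3 peaks that overlapped an H3K27me3 region by at least 1 bp ranked lower by fold than the other peaks of their lists. They made up 14.9% of replicate 1 (4455 peaks) and 14.8% of replicate 2 (4069 peaks). With H3K27me3 replicate 1 alone they made up 24.7% and 23.3%, and with a −log10 q of at least 5 they made up 4.33% and 4.04%. Their median rank by fold was in the 23.8th percentile in replicate 1, against the 55.9th for the other peaks, and in the 34.6th against the 53.0th in replicate 2. They were also narrower, with medians of 526 bp against 577 bp and 389 bp against 437 bp. In 1000 rotations of the overlap labels along the chromosomes, no difference in rank or in width was as large (two-sided permutation p = 0.0020 in each list, the smallest the rotations can give).

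At the boundaries of H3K27me3 regions of at least 2000 bp, H3K4me3 centres were nearly missing from the 500 bp outside and frequent just inside. There were 0.0112 centres per kb in the 500 bp outside, 0.127 per kb in the 500 bp inside the boundary and 0.106 per kb in the interior, counted over 2146 regions. Placement of the regions within 500 kb gave 0.0808, 0.0827 and 0.0830 per kb, so the observed densities were 0.138, 1.54 and 1.28 times the placed ones (permutation p = 0.020 each). The density inside was 11.4 times that outside, with placed ratios between 0.808 and 1.23. The lack outside held in all settings tried. The excess inside did not: with a −log10 q of at least 5 the inside edge and the interior were at 1.30 and 1.12 times the placed density (permutation p = 0.059 and 0.079), and for regions of at least 5000 bp at 1.16 and 1.04 times (permutation p = 0.42 and 0.44). The ratio of inside to outside varied in size, with only 24 centres outside. It was 26.4 with H3K27me3 replicate 1 alone, where 15 centres lay outside, and 28.3 with a −log10 q of at least 5, where 4 did. Of the 4292 boundaries, 53 fell within an H3K4me3 region, against a mean of 168.5 (range 135 to 200) after placement, a ratio of 0.314. This ratio was 0.547 with H3K4me3 replicate 1 alone, 0.167 with H3K27me3 replicate 1 alone and 0.175 with a −log10 q of at least 5.

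**Figure D3:**
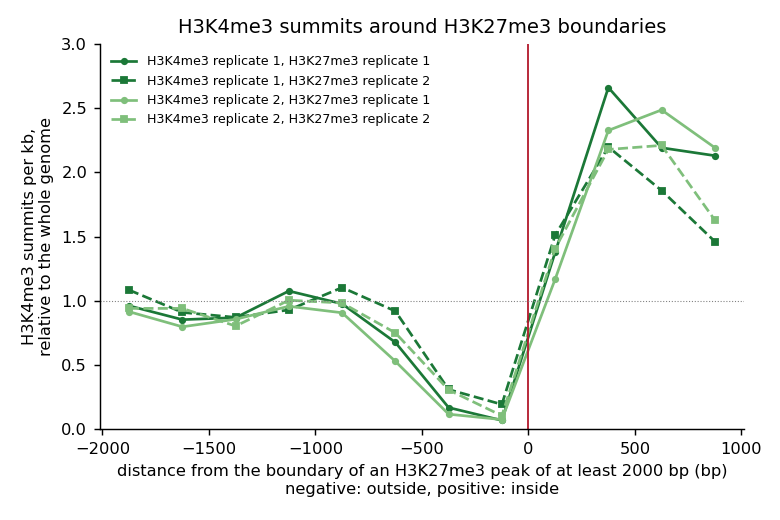
Density of H3K4me3 summits, relative to the whole genome (vertical axis), by distance in bp from the nearest end of an H3K27me3 peak of at least 2000 bp (horizontal axis, negative outside, positive inside, in steps of 250 bp), for each of the 4 pairings of libraries. In the 250 bp outside the boundary the relative density was 0.069 to 0.194, and from 250 to 500 bp inside it was 2.18 to 2.66.

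At the scale of 100 kb, the windows poorest in H3K4me3 were also poor in H3K27me3. In 3723 windows sorted into 5 equal groups by H3K4me3 coverage, mean H3K27me3 coverage was 2.26% in the lowest group, 4.56% and 5.72% in the next, 5.89% in the fourth and 5.07% in the highest. The lowest group minus the fourth gave −3.62 percentage points (rotation of windows along the genome, permutation p = 0.0020, the smallest possible). With a −log10 q of at least 5 this difference was −1.72 points, at lower coverage throughout (permutation p = 0.0020). Assembly gaps, in which no peak can be called, and repeats, in which peaks may be missed, can lower both marks in a window and were not checked. The rotations do not control for them. From the fourth to the highest group coverage fell by 0.815 points (permutation p = 0.048). In windows of 500 kb the difference was −0.0983 points (permutation p = 0.86). It no longer passed 0.05 with a −log10 q of at least 5, at −0.441 points (permutation p = 0.082), or without H3K27me3 replicate 2, where it was larger, at −0.938 points (permutation p = 0.080).

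The chromosomes differed widely in H3K4me3 and little in H3K27me3. H3K4me3 regions covered 1.89% of chromosome 11 and 2.00% of chromosome 12, the lowest values, and 4.60% of chromosome 3 and 4.13% of chromosome 1, the highest, a 2.43-fold range. H3K27me3 regions ranged 1.21-fold, from 4.31% of chromosome 12 to 5.23% of chromosome 1. The order of the 2 lowest and 2 highest chromosomes for H3K4me3 was the same in both libraries, with chromosome 11 at 3.22% and 2.14% and chromosome 3 at 6.90% and 5.11%. The length of H3K27me3 per length of H3K4me3, relative to the whole genome, was 1.77 on chromosome 11 (1.65 to 1.78 over the 4 pairings of libraries), 1.51 on chromosome 12 (1.38 to 1.53) and 0.713 on chromosome 3 (0.710 to 0.747). No test was made between chromosomes.

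**Figure D4:**
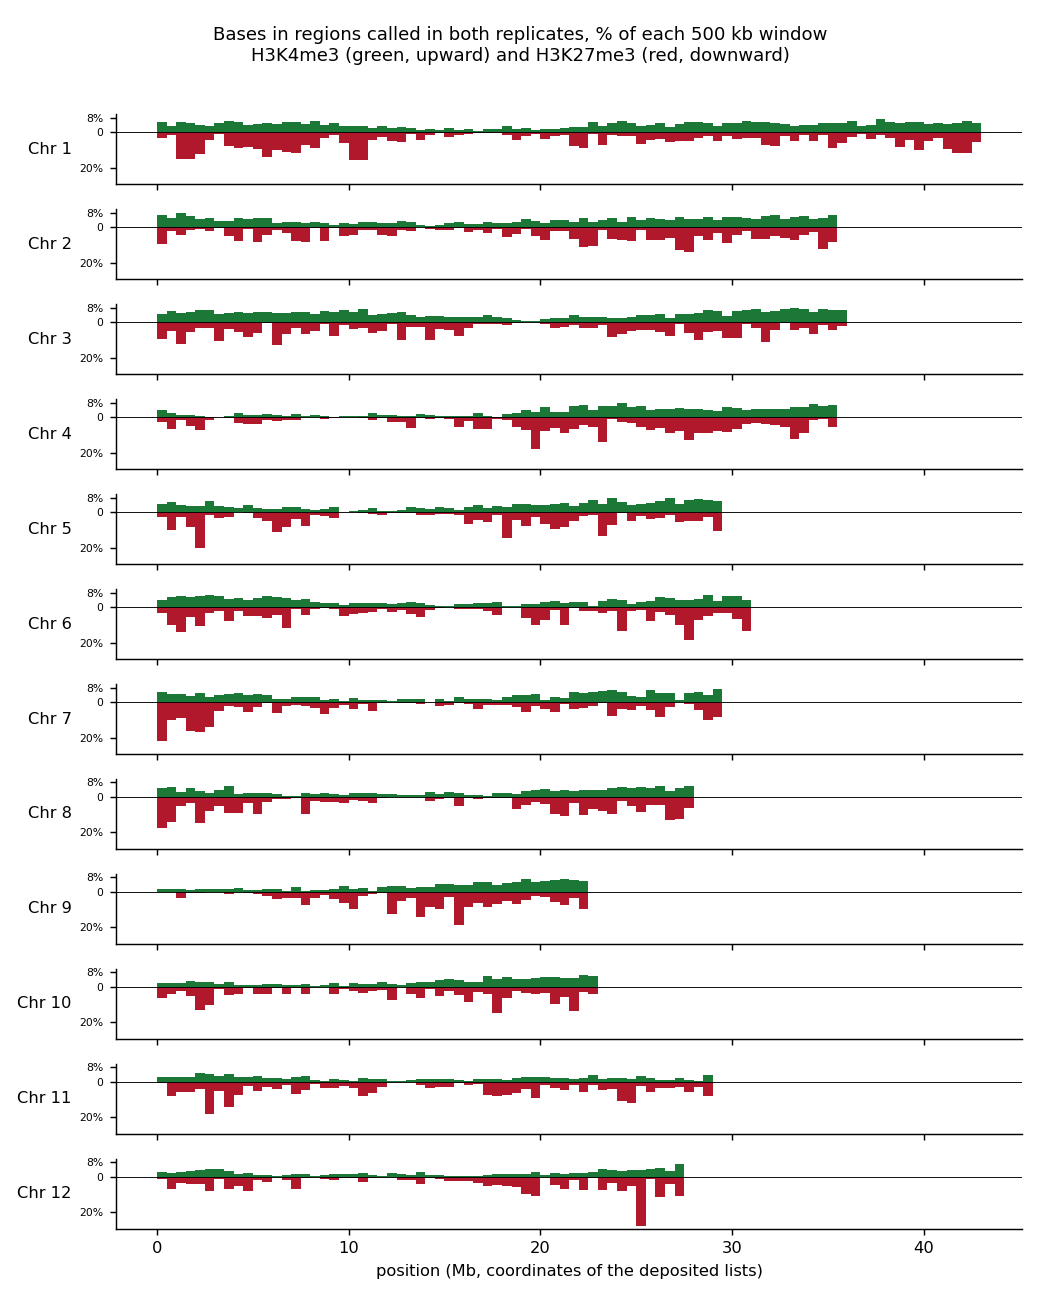
Percentage of bases in H3K4me3 regions (green, upward) and H3K27me3 regions (red, downward) in windows of 500 kb along the 12 chromosomes (horizontal axis in Mb, coordinates of the deposited lists). The highest H3K27me3 window, 27.9%, starts at 25 Mb on chromosome 12, and the highest H3K4me3 window, 8.10%, at 24 Mb on chromosome 4.

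The H3K27me3 replicates differed in where their unshared peaks lay. The 6477 peaks found in replicate 1 alone had 39.1% of their bases in peaks of H3K4me3 replicate 1 and 23.5% in peaks of H3K4me3 replicate 2, whereas the 3932 peaks found in replicate 2 alone had 0.833% and 1.26%. Against placement within 500 kb, the share in regions of H3K4me3 was 6.06 times the placed value for the former and 0.174 times for the latter (permutation p = 0.020 each). Peaks found in both H3K27me3 replicates lay between these, at 1.91 times the placed value with the replicate 1 coordinates and 1.78 times with those of replicate 2. The values of the 2 unshared sets are not independent. A replicate 2 peak counts as unshared only where replicate 1 had none, and replicate 1 peaks overlapped 24.7% of the H3K4me3 replicate 1 peaks. The low value of the replicate 2 set can therefore follow from the high one of the replicate 1 set. These unshared peaks do not enter the regions of both replicates used above. With the whole list of H3K27me3 replicate 1 in place of these regions the ratio of shared bases within 500 kb was 2.42, and with that of replicate 2 it was 1.67.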

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

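The alternatives for the comparison of peak number, width and coverage, for region length, ranks, boundaries, windows, chromosomes and peak rank, and those with placement within 500 kb, were chosen after seeing the data. Of 96 alternatives, 74 kept direction and side of the threshold (or moved less than the spread), 15 values moved, 5 lost significance and 2 reversed. For boundaries this tally counts only the ratio of inside to outside, so the excess inside that was lost in some settings is not in it. With a −log10 q of at least 5, H3K27me3 minus H3K4me3 was −20126 peaks, 1353 bp in median width and −3.61 Mb in covered length, the last of opposite sign to the 7.08 Mb of the authors' thresholds. Each share of peaks found in the other replicate stayed above all placements. With that threshold it fell in the replicate 1 lists, from 79.4 to 63.1% for H3K4me3 and from 67.2 to 47.3% for H3K27me3. In the replicate 2 lists it rose, from 93.3 to 95.7% and from 79.8 to 82.2%. The ratio of shared bases ran from 1.92 to 2.79 when replicates were left out, and from 1.67 to 2.42 with placement within 500 kb. The gap in shared peaks between the highest and lowest of 4 groups by fold moved, with 50% reciprocal overlap, to 45.2 points in H3K4me3 replicate 1, 27.1 in H3K4me3 replicate 2 and 57.1 in H3K27me3 replicate 1. With a −log10 q of at least 5 it was 55.7, 1.58, 68.7 and 1.31 points in H3K4me3 replicates 1 and 2 and H3K27me3 replicates 1 and 2. The relative amount of H3K27me3 with that threshold was 1.48 on chromosome 11, 1.59 on chromosome 12 and 0.687 on chromosome 3. Leaving out replicates gave 1.62 to 1.82, 1.42 to 1.53 and 0.711 to 0.745 there. The overlap in bases in H3K27me3 regions of 5000 bp and over, below the placed value in the main setting, ranged from 0.801 to 1.06 times that value without each replicate. With a −log10 q of at least 5 it was 0.718, and that under 500 bp fell to 1.09. The difference in H3K27me3 between the highest and the fourth of 5 groups of windows was −0.441 points with a −log10 q of at least 5 (permutation p = 0.082), −0.0983 in windows of 500 kb, and −1.32 to −0.936 without each replicate, with permutation p = 0.080 without H3K27me3 replicate 2. The cause was not tested, except that the stricter threshold leaves fewer peaks by construction. With the replicate number as a block, pairing same-numbered libraries, the ratio of shared bases was 2.56, and with the crossed pairs it was 2.41. The correlation of the replicate differences of the marks over 3723 windows was 0.122. With 2 pairs the samples share only a number, and the block changed no call. Of 25 alternatives fixed before the data were examined, the 21 that concern genes were not run. The only gene table used here did not lie on the coordinates of the lists. Unknown depth limits what the absence of a peak means.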

Other observations

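All tests in this part were chosen after the lists were seen, and the tests on overlap of the marks and on boundaries after their results were seen.

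Long stretches without H3K4me3 regions of both replicates were poor in H3K27me3 regions as well. The longest gap between H3K4me3 regions on each chromosome measured 256.5 to 641.7 kb, the largest on chromosome 6 from 18165268 to 18806991, and the 12 gaps together held 5.30 Mb. H3K27me3 regions covered 0.502% of them, against 4.70% of the genome, and 4 of the 12 held none. Of the 12 gaps, 8 held H3K4me3 peaks of single libraries. The gap on chromosome 9 from 6438890 to 6939526 was the exception at 2.81%, with 39 and 33 H3K27me3 peaks in the 2 replicates. Assembly gaps and repeats were not checked here. H3K4me3 was most lopsided on chromosomes 4, 9 and 10. Above the midpoint of chromosome 4 (17.8 Mb) H3K4me3 regions covered 4.73% and below it 1.03%, a ratio of 4.57 (4.24 and 4.55 in the 2 libraries), and for H3K27me3 the ratio was 2.75. On chromosome 9 the ratios were 3.31 and 2.70, and on chromosome 10 they were 2.61 and 1.44. H3K27me3 was more lopsided on chromosomes 12 and 2 than on chromosome 10, with ratios of 1.99 and 1.88. On chromosomes 3, 6 and 11 H3K4me3 ratios were 0.899, 0.887 and 0.898.

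Of the 10 windows of 100 kb densest in H3K27me3, 4 overlapped 1 of the 10 longest regions. The densest, from 13.9 to 14.0 Mb on chromosome 9, had 55.0% of its bases in H3K27me3 regions (59.9% and 56.1% in the 2 replicates) and 2.68% in H3K4me3. It was followed by 1.5 to 1.6 Mb on chromosome 7 (49.3%), 6.0 to 6.1 Mb on chromosome 3 (47.5%), 17.8 to 17.9 Mb on chromosome 10 (45.2%) and 1.6 to 1.7 Mb on chromosome 1 (44.1%). H3K4me3 regions covered 0.754 to 5.72% of these 10 windows, and 8 of the 10 lay below the genome's 3.28%. The highest was the window on chromosome 7.

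The H3K27me3 peaks found in replicate 1 alone lay in H3K4me3 peaks far more often than those found in replicate 2 alone. If H3K4me3-type signal carried into that library were seen first at the tallest H3K4me3 peaks, the peaks touched would rank high. The 2667 H3K4me3 replicate 1 peaks they touched had a median rank in the 29.3rd percentile by fold. However, peaks of that list overlapping the H3K27me3 regions of both replicates also ranked low, in the 23.8th percentile. The rank therefore does not decide on carried signal. Fold and width in replicate 1 do not account for it. Over 6314 pairs matched on both, the unshared peaks had 38.6% of their bases in H3K4me3 replicate 1 and the shared peaks 15.7%, a difference of 22.8 points. The shared peaks were also called in replicate 2, so this matching does not make the pairs equal in strength. Carried signal and weakness of the peaks stay open. Also open, and untested, are a difference in handling of the 2 libraries before calling, an uneven recovery of accessible chromatin, and a difference between the biological samples. No biological explanation was tested.

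The 2 marks shared more bases than random placement gave. At the scale of 500 kb, both marks lying in the same parts of the chromosomes does not account for all of it, with a ratio of 1.96. Finer stretches were not tested, and these placements ignore assembly gaps and repeats, so their expectation may be too low. With the same limit, the ratio was 1.67 without H3K27me3 replicate 1. With a −log10 q of at least 5 it was 1.28, so most of the excess was lost with the weaker peaks. That cut also removed most short regions, and at 500 to 1000 bp and 1000 to 2000 bp the ratio was 3.11 and 2.41 with it. The fall can therefore not be assigned to weak peaks apart from region length, and no alternative combined all of these. No biological explanation was tested. Bias of both antibodies toward accessible chromatin was not tested and remains open, as no input values were used.

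H3K4me3 centres were scarce just outside H3K27me3 regions of at least 2000 bp. If the called regions simply ran on a short way past the H3K4me3 peaks at their margins, the centres missing outside would reappear within 500 bp inside. The sum over the 500 bp on both sides would then lie within the placed range. The sum was 0.847 times the placed mean (297 centres, placed 303 to 399), and it was also below the placed range at 0.807 and 0.788 times without H3K27me3 replicates 1 and 2 and at 0.669 times with a −log10 q of at least 5, where 83.7 centres were missing outside and 25.9 in excess inside. It was within the placed range at 0.890 times without H3K4me3 replicate 1 (permutation p = 0.040) and at 0.948 times without H3K4me3 replicate 2 (permutation p = 0.30). By that range the values argue against a shift of at most 500 bp as the whole cause in 4 of the 6 settings and leave it open in the other 2. A longer shift would put the centres in the interior, which the sum leaves out and where the density was 1.28 times the placed one. The sum therefore does not decide on a longer shift either. A shift of either length and a true lack of H3K4me3 next to these regions cannot be told apart here, and no biological explanation was tested.

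A site on chromosome 11 from 12351954 to 12352962, within the longest gap between H3K4me3 regions of that chromosome (12077376 to 12640349), had the highest fold enrichment in H3K4me3 replicate 1 (30.3, the next peak 16.3) and in H3K27me3 replicate 2 (12.3, the next 9.26). H3K4me3 replicate 2 had no peak there, and in H3K27me3 replicate 1 the peak had a fold of 3.09 and was number 2467 of the list by fold.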
